A study of Bos taurus with 6 samples.

How the data were processed

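Cumulus cells were removed mechanically from cumulus-oocyte complexes of cow ovaries collected after slaughter, and RNA from pooled cells was labelled with biotin and hybridised to Affymetrix bovine arrays, per the labels. There were 6 arrays, 3 of complexes from follicles of 8 mm or more (large_follicle) and 3 of complexes from follicles of 1 to 3 mm (small_follicle). The deposited values are log2 probe set signals, which the authors made with RMA per the submitters' processing notes. The software, its version and its settings are not given in the sources used here. The values run from 1.80 to 14.39 with 2 decimals, and the medians of the arrays lie between 5.64 and 5.68.

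The table holds 24128 probe sets. The 112 control probe sets were left out of the gene tests, which leaves 24016. Of these, 13292 carry 1 gene symbol, 86 several and 10638 none in the annotation used here, and the symbols name 9154 genes. Gene identifiers were matched to the RefSeq annotation of ARS-UCD2.0 for names only, which matched 13263 probe sets and changed 2 symbols. Probe sets without a symbol, GREM1 among them, count in the totals and are not named.

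Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior variance, no block), as large_follicle minus small_follicle, with 2-sided moderated t tests and Benjamini-Hochberg adjustment over the 24016 probe sets at a threshold of 0.05. The prior degrees of freedom were 4.28 and the total 8.28. No filter on low values was used, since RMA gives no detection call. Array number, with 3 arrays per group, limits the precision. Similarity between arrays was read as Pearson correlation and principal components. Correlations lay between 0.9927 and 0.9948 within groups and between 0.9817 and 0.9879 across groups, and the first component held 57.5% of the variance.

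Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, on 1 probe set per gene, the one with the highest mean. Benjamini-Hochberg adjustment ran over the 24 of 29 lists with at least 10 measured genes. Camera is a 2-sided test of the list against all other genes. The lists covered the mitotic cell cycle, DNA replication and repair, meiosis, energy and lipid metabolism, gonadotropin response and steroidogenesis, cumulus expansion, growth factor signalling, cell contacts, matrix, inflammation, interferon response, antioxidants, apoptosis, the unfolded protein response, handling genes, ribosomal proteins and markers of 8 cell types. The groups, the test, the lists, the rule for named genes and the alternatives were fixed before the data were examined.

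The rule named the 12 genes with the largest increase and the 12 with the largest decrease among called probe sets with 1 symbol whose groups do not overlap, each gene read from its probe set with the smallest p. It also named up to 4 members with the smallest p of each list that passed or held a called gene (up to 3 for cell type and handling lists), and a fixed set of ovarian genes whatever their result. Symbols that are only locus, reading frame or clone names were skipped. The 3'-minus-5' index is the mean over 6 bovine control transcripts of the 3' minus the 5' probe set, compared by an exact permutation test.

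The alternatives set beforehand were a replicate block, leaving out each array, filters at the median and the lower quartile, quantile, median and cyclic loess scaling, array weights, a trended robust prior, leaving out probe sets that can bind several transcripts, other thresholds, 1 mean per gene, an estimated correlation, and fry. Covariates for the 3'-minus-5' index and for the leukocyte markers, and a fit of replicates 1 and 2 only, were chosen after seeing the data. The procedure was tested on simulated data with known changes, and it recovered 22.4% of 67 probe sets at a log2 size of 0.5, 77.6% of 67 at 1 and 97.0% of 66 at 2, with 8 false calls among 23816 unchanged probe sets. The simulated probe sets varied independently, and far fewer changed than were called in the data. These rates need not hold for the real comparison. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.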

Results

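Gene expression was measured in bovine cumulus cells, the somatic cells that enclose the oocyte inside the follicle. RNA from pooled cumulus cells of crossbred cows was hybridised to 6 Affymetrix bovine arrays. In 3 arrays the complexes came from follicles of 8 mm or more, called competent by the submitters, and in the other 3 from follicles of 1 to 3 mm, called incompetent. The comparison asks which transcripts of cumulus cells differ with the size of the follicle, which the study uses as a stand-in for the developmental capacity of the oocyte. The values are log2 signals, and 24016 probe sets remained after control probe sets were left out. The medians of the arrays lay between 5.64 and 5.68. The titles call the arrays of a group biological replicates, but how many cows or complexes stand behind each pool is not given in the sources used here, so p-values measure the spread between these pools. The number of arrays limits the precision.

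Cumulus cells of large follicles had more transcript of the steroidogenic enzymes CYP19A1 and CYP11A1, of the activin subunit INHBA and of the glucose transporter SLC2A1, and less of the chaperone genes DNAJB1 and HSPA1A and of the imprinted gene MEST. CYP19A1, the aromatase that makes oestrogens, averaged 12.25 ± 0.46 (SD, n = 3) in large-follicle arrays and 10.12 ± 0.20 (SD, n = 3) in small-follicle arrays, 4.40-fold higher by limma (2.46-fold by a second, dimmer called probe set). SLC2A1 averaged 11.70 ± 0.18 against 9.51 ± 0.35 (SD, n = 3 each), 4.56-fold higher. DNAJB1, a co-chaperone of the HSPA heat shock proteins, averaged 8.93 ± 0.23 against 11.72 ± 0.17 (SD, n = 3 each), 6.90-fold higher in small-follicle arrays (8.21-fold by its other probe set). MEST averaged 9.96 ± 0.09 against 12.71 ± 0.24 (SD, n = 3 each), 6.74-fold higher in small-follicle arrays.

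In the limma fit with Benjamini-Hochberg adjustment over all 24016 probe sets, 1374 probe sets were higher and 1720 lower in large-follicle arrays at the 0.05 threshold, 12.9% of those tested. At least 2-fold differences were found in 291 of the higher and 202 of the lower ones. The groups did not overlap in 7428 probe sets, 30.9% of those tested, where labels given at random give 10% on average. Probe sets vary together, so a single random grouping can lie far from 10%, and that spread was not computed. By gene symbol, 765 genes rose and 838 fell, and 6 had probe sets called in both directions. The number of calls moved with single arrays: 851 and 947 probe sets (higher and lower) were called without large-follicle replicate 1, 867 and 1066 without large-follicle replicate 2, 843 and 1051 without small-follicle replicate 1, and 787 and 828 without small-follicle replicate 2. None of the calls changed sign in these fits. That outcome was fixed beforehand, since the groups overlapped in no called probe set, and leaving out an array then cannot reverse the difference.

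**Figure D1:**
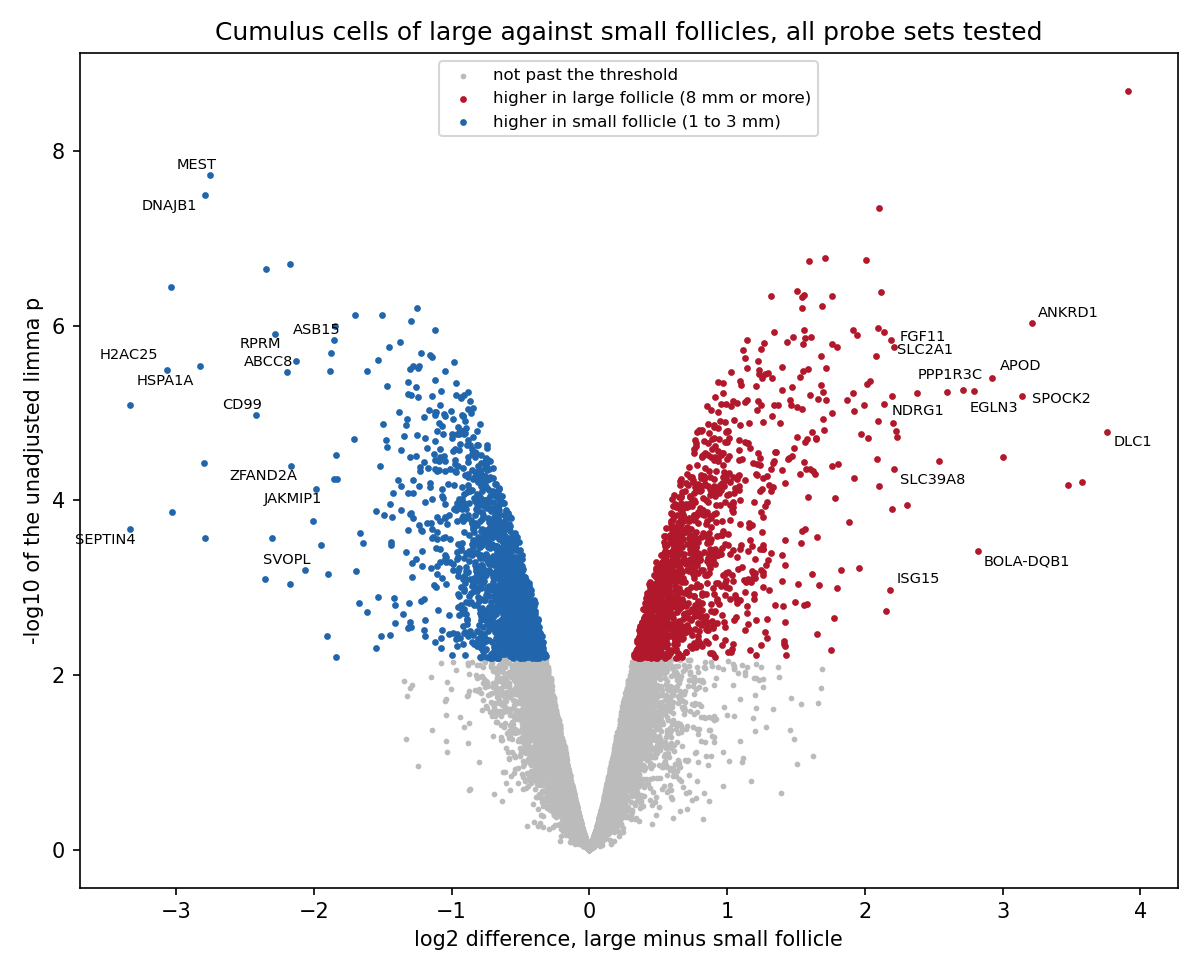
Each point is 1 of the 24016 probe sets, with the log2 difference (large minus small follicle) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis; red and blue points passed the Benjamini-Hochberg threshold of 0.05. The 1374 higher and 1720 lower probe sets lie on both sides, and the named genes are the 12 in each direction that the rule for named genes picked, each at its probe set with the smallest p.

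Read from each gene's probe set with the smallest p, the largest named increases were in DLC1 at 3.76 ± 0.42 (log2 difference ± SE), ANKRD1 at 3.21 ± 0.25, the extracellular proteoglycan SPOCK2 at 3.14 ± 0.31, and the lipid carrier APOD at 2.92 ± 0.27. DLC1 averaged 3.07 and SPOCK2 2.73 in small-follicle arrays, below the lower quartile of probe set means (3.83), so these differences are less certain in size. The major histocompatibility class II gene BOLA-DQB1 rose by 2.82 ± 0.49, EGLN3, a prolyl hydroxylase, by 2.79 ± 0.27, NDRG1 by 2.71 ± 0.26 and PPP1R3C, a glycogen-targeting phosphatase subunit, by 2.60 ± 0.26. The other probe sets of PPP1R3C read 3.57 ± 0.48, at the brightest of the 3 (9.37 against 5.80), and 3.48 ± 0.47, so its size and its place in this order depend on the probe set. Second called probe sets read less for ANKRD1 (2.23), APOD (2.23) and FGF11 (1.97). SLC39A8 and FGF11 rose by 2.21 each, and ISG15, a ubiquitin-like interferon product, by 2.18 ± 0.44. Read the same way, the largest named decreases were in SEPTIN4 at -3.34 ± 0.53, the histone gene H2AC25 at -3.07 ± 0.28, HSPA1A at -2.83 ± 0.25, DNAJB1 at -2.79 ± 0.14 and MEST at -2.75 ± 0.13. Other called probe sets read -3.04 for DNAJB1, -3.03, -2.30 and -0.62 for HSPA1A, -1.87 for MEST, -1.11 for CD99 and -1.51 for ZFAND2A, so sizes and order among these genes are not fixed. Further probe sets of MEST (-0.16 and -0.26), H2AC25 (-0.21), HSPA1A (-0.20 and -0.42), APOD (-0.02) and BOLA-DQB1 (0.35 to 1.20) did not pass. HSPA1A has near-identical copies in cattle, so its probe sets can read more than 1 gene. CD99 followed at -2.42, RPRM at -2.28, the potassium channel regulator ABCC8 at -2.19, ZFAND2A at -2.16, SVOPL at -2.07, JAKMIP1 at -1.98 and ASB15 at -1.85.

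The arrays also differed in a sign of RNA quality. The difference between 3' and 5' probe sets, averaged over 6 bovine control transcripts, was 1.98 ± 0.19 log2 units (SD, n = 3) in large-follicle arrays and 2.46 ± 0.27 (SD, n = 3) in small-follicle arrays, a difference of -0.48 (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 arrays allow). With this index as a covariate, chosen after the data were seen, limma called 99 probe sets higher and 116 lower. The median size of the difference over the 3094 probe sets called without it went from 0.64 to 0.57, while the median SE went from 0.12 to 0.18, and all 3094 kept their sign.

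**Figure D2:**
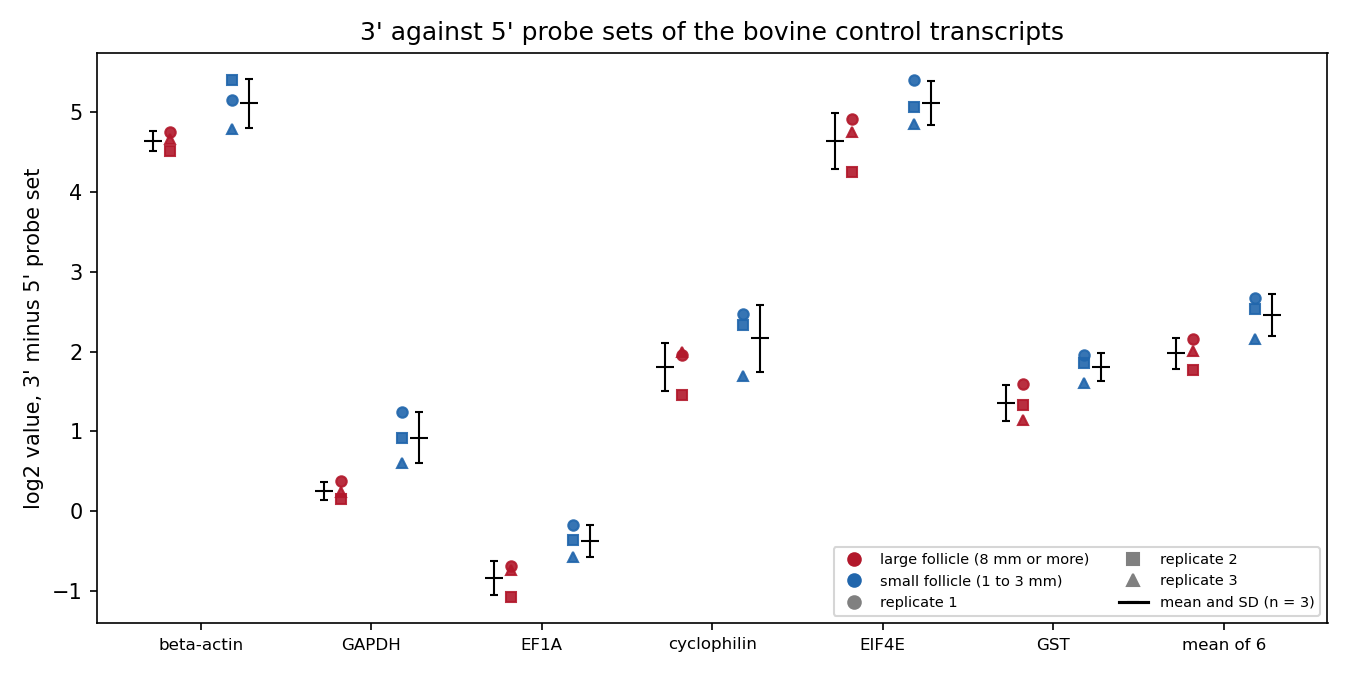
For each of 6 bovine control transcripts and their mean, the vertical axis gives the log2 value of the 3' probe set minus that of the 5' probe set; coloured points are arrays (shape gives the replicate) and black bars the mean and SD of each group (n = 3). The mean over the transcripts was 1.98 in large-follicle and 2.46 in small-follicle arrays.

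Genes of glycolysis rose: of 19 measured, 15 were higher, 0 lower and 4 did not pass. Adjusted over the list alone, 17 were higher. SLC2A1 rose by 2.19 ± 0.18, PFKP, a phosphofructokinase, by 1.36 ± 0.16, LDHA, a subunit of lactate dehydrogenase, by 0.75 ± 0.10, and PFKL by 0.76 ± 0.12. By camera, the Benjamini-Hochberg adjusted p was 9.97e-10, against an adjusted p = 0.462 with an estimated correlation. With the 3'-minus-5' index as a covariate the mean difference was 0.55, against 0.78 without it, and camera's adjusted p was 1.95e-06. Of 29 measured genes of oxidative phosphorylation and the TCA cycle, 0 were higher and 1 was lower, IDH2 at -0.77 ± 0.11, and adjusted over the list alone 1 was lower (camera adjusted p = 0.31).

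Genes of gonadotropin response and steroidogenesis were higher: of 23 measured, 9 rose, 1 fell and 13 did not pass, and adjusted over the list alone 11 rose and 1 fell. INHBA rose by 1.14 ± 0.10 (limma Benjamini-Hochberg adjusted p = 0.00107), CYP11A1, which makes pregnenolone from cholesterol, by 1.72 ± 0.16, CYP19A1 by 2.14 ± 0.22 and the transcription factor GATA4 by 0.76 ± 0.09. The 1 member that fell was PGRMC1, a progesterone-binding membrane protein, at -0.48, named after its value was seen. Camera's Benjamini-Hochberg adjusted p was 3.12e-05, with adjusted p = 0.455 with an estimated correlation. With the 3'-minus-5' index as a covariate the mean was 0.45 and camera's adjusted p 0.00206. The follicle-stimulating hormone receptor FSHR rose by 0.56 ± 0.13, a call lost without large-follicle replicate 1 (0.61), 2 (0.51) or 3 (0.56), without small-follicle replicate 1 (0.56) or 2 (0.46), and with the index (0.29) or the leukocyte markers (0.53) as a covariate. The luteinising hormone receptor LHCGR, at 0.31 ± 0.11, and AMH, at -0.06 ± 0.10, did not pass. LHCGR averaged 3.85 against 3.54, a low signal on these arrays.

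The markers of granulosa and cumulus cells share 10 measured genes with that list. Of 13 measured, 6 rose, 1 fell and 6 did not pass, and adjusted over the list alone 7 rose and 1 fell. Those that rose were INHBA, CYP11A1, CYP19A1, FSHR, NR5A2 and INHA, and GATM, which makes a creatine precursor, fell by 1.20. NR5A2, INHA and GATM were picked after their values were seen. Camera's Benjamini-Hochberg adjusted p was 0.00142, with adjusted p = 0.462 with an estimated correlation. The mean was 0.47, and 0.41 with the 3'-minus-5' index as a covariate, with camera's adjusted p at 0.0136.

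Among cumulus expansion and ovulatory genes 18 were measured, 2 rose, 3 fell and 13 did not pass, and adjusted over the list alone 3 rose and 3 fell. PTGS2, the inducible prostaglandin synthase, fell by 1.28 ± 0.20, the proteoglycan HSPG2 by 0.79 ± 0.13, and BTC, an EGF-like growth factor, by 0.96 ± 0.17. VCAN rose by 0.52 ± 0.12. The mean difference was 0.06 while camera's direction was down, with a Benjamini-Hochberg adjusted p = 0.976. HAS2, the hyaluronan synthase, gave opposite results: its probe set with the highest signal read -0.31 ± 0.11 (limma Benjamini-Hochberg adjusted p = 0.113), another -0.63 (adjusted p = 0.016) and a dimmer one 0.87 (adjusted p = 0.0455). PTX3 at 0.22 ± 0.53, TNFAIP6 at 1.45 ± 0.61 (0.93 without large-follicle replicate 1 and 0.79 without small-follicle replicate 1), AREG at 0.11 ± 0.13 and FST at 0.23 ± 0.09 did not pass. GREM1 carries no gene symbol in the annotation used here and is not reported.

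Genes of DNA replication and of the mitotic cell cycle were lower. Of 21 replication genes, 0 rose, 10 fell and 11 did not pass, and 17 fell adjusted over the list alone. MCM6, MCM7 and MCM4, subunits of the replicative helicase, differed by -0.72, -0.88 and -0.75, and TYMS, the thymidylate synthase, by -0.78. Of 22 mitotic genes, 5 fell and 17 did not pass, and 15 fell adjusted over the list alone, among them NUSAP1 at -0.82, CCNA2 at -0.91, MAD2L1 at -0.46 and CKS2 at -0.63. Camera's Benjamini-Hochberg adjusted p was 4.92e-07 for replication and 3.8e-06 for the mitotic cell cycle. Both had adjusted p = 0.591 with an estimated correlation (0.839 for replication and 0.853 for the mitotic cell cycle). The mean of the mitotic genes was 0.07 above the mean of all arrays in large-follicle replicate 3 and -0.02 in small-follicle replicate 3, so the 2 groups overlapped there. For replication these 2 arrays lay close together, at 0.001 and 0.035, without an overlap. With the 3'-minus-5' index as a covariate the mitotic genes no longer passed (mean -0.18, adjusted p = 0.115), against -0.24 and 0.0363 for replication.

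**Figure D3:**
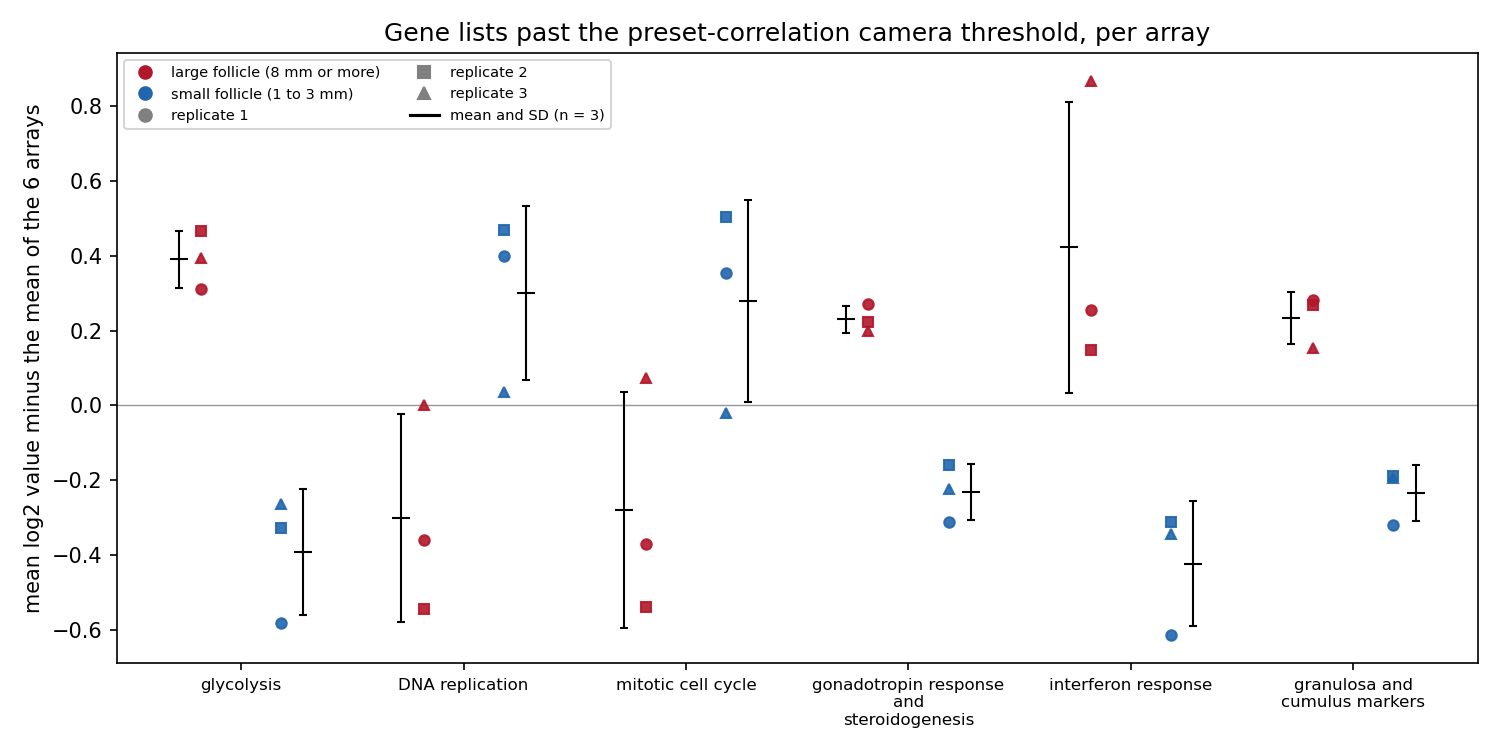
For the 6 gene lists that passed the camera threshold with the preset correlation, the vertical axis gives each array's mean log2 value over the list minus the mean of all 6 arrays; coloured points are arrays (shape gives the replicate) and black bars the mean and SD (n = 3). Glycolysis is higher in every large-follicle array, whereas large-follicle and small-follicle replicate 3 lie close together for the mitotic cell cycle at 0.07 and -0.02.

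Interferon response genes were higher. Of 14 measured, 7 rose, 0 fell and 7 did not pass, and adjusted over the list alone 8 rose. IRF9, a subunit of the transcription factor ISGF3, rose by 1.56 ± 0.18, ISG15 by 2.18 ± 0.44, RSAD2 by 0.81 ± 0.19 and IRF7 by 0.86 ± 0.21. Camera's Benjamini-Hochberg adjusted p was 0.000175, with adjusted p = 0.591 with an estimated correlation. The mean was 0.85, and 0.81 with the 3'-minus-5' index as a covariate, with camera's adjusted p at 0.00382. The list's mean was highest in large-follicle replicate 3, at 0.87 above the mean of all arrays, against 0.25 and 0.15 in the other large-follicle arrays. Leukocyte markers moved with the groups as well: of 16 measured, 2 rose (CORO1A by 0.62 and LCP1 by 0.89), 0 fell, 14 did not pass and 2 rose adjusted over the list alone (camera's Benjamini-Hochberg adjusted p = 0.0515). All 16 were higher in sign, with a mean of 0.49, and CD14 read 1.02 ± 0.54 and did not pass (0.43 without large-follicle replicate 1, and 1.63 with a call without large-follicle replicate 3). CORO1A averaged 4.30 against 3.67 and LCP1 4.78 against 3.89, low signals on these arrays. The leukocyte list passed camera in 7 of 20 other settings. Its mean was 0.16 without large-follicle replicate 1, and it passed without large-follicle replicate 2 (0.59) or 3 (0.72), without small-follicle replicate 3 (0.72), and in replicates 1 and 2 only (0.95). The list's mean per array was highest in large-follicle replicate 1, at 0.90, and was -0.22 in large-follicle replicate 3.

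Immediate early and heat shock genes went both ways. Of 22 measured, 4 rose, 9 fell and 9 did not pass, and adjusted over the list alone 4 rose and 10 fell (camera's Benjamini-Hochberg adjusted p = 0.0825, with adjusted p = 0.591 with an estimated correlation). DNAJB1 fell by 2.79 and HSPA8, a constitutive chaperone, by 0.81, whereas JUNB, a transcription factor, rose by 0.97 ± 0.09. Among 21 DNA repair genes 1 rose and 5 fell, with 1 and 6 adjusted over the list alone (camera's Benjamini-Hochberg adjusted p = 0.0825). CHEK1, a checkpoint kinase, fell by 1.09 and UNG, the uracil-DNA glycosylase, by 0.62, FANCI by 0.75, and GADD45A rose by 0.59. Of 20 listed meiosis genes only 4 were measured and 0 passed, adjusted over the list alone as well.

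Other lists held single changes and did not pass camera with Benjamini-Hochberg adjustment. Of 17 genes of cholesterol synthesis and uptake 2 rose, SQLE by 0.96 ± 0.12 and the lipoprotein receptor SCARB1 by 0.63 (adjusted over the list alone 2 rose and 2 fell, camera adjusted p = 0.0892), and EBP at -0.63 and MVK at -0.44 did not pass. Of 17 genes of fatty acid oxidation and synthesis 2 rose, among them the lipid droplet protein PLIN2 by 1.55 ± 0.13 and FABP3 by 0.83, and 3 fell, including FASN by 0.69 and ACSL3 by 0.60 (the same counts adjusted over the list alone, camera adjusted p = 0.418). Among 18 genes of IGF and growth factor signalling 2 rose and 2 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.316): IGFBP4 by 1.80 ± 0.15, VEGFA by 1.18 ± 0.19, and on the lower side the receptor KIT at -1.43 ± 0.20 and IGF2R at -0.41. Among 25 extracellular matrix genes 2 rose and 5 fell, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.426), with FBN1 at -1.62, LAMC1 at -0.82, COL6A1 at -0.86 and TIMP2 at 0.50. The 3'-minus-5' index as a covariate brought 3 lists past camera's Benjamini-Hochberg threshold: cholesterol synthesis and uptake (mean 0.38 against 0.17, adjusted p = 0.00523 in a range of 0.00523 to 0.718 over the alternatives, mean 0.07 to 0.26 leaving out 1 array), extracellular matrix (-0.33 against -0.14, adjusted p = 0.0462 in a range of 0.0152 to 0.922, mean -0.23 to -0.001 leaving out 1 array), and inflammation and NF-kB (0.25 against 0.17, adjusted p = 0.0462 in a range of 0.0462 to 0.718, mean 0.08 to 0.23 leaving out 1 array).

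Of 22 genes of BMP and TGF-beta signalling, 3 rose, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.272): ID2 by 1.04, BMPR2 by 0.52 and BMPR1B by 0.54, the last at a low signal. The other ID2 probe set read -0.58 and did not pass, and those of BMPR2 read 0.03 and 0.09. ID1, at -0.49, did not pass. Of 13 gap junction and cell contact genes NPR2 rose by 0.52 and GJC1 fell by 0.89 (camera adjusted p = 0.972, with 2 and 1 adjusted over the list alone), and FSCN1 at 0.33 and DAAM1 at 0.39 did not pass. In inflammation and NF-kB, 26 genes were measured and 3 rose (CD40 by 0.76, VCAM1 by 0.76, S100A9 by 0.42) and SOD2 fell by 0.42, the same counts adjusted over the list alone (camera adjusted p = 0.234). Among 18 antioxidant and glutathione genes 3 rose and 2 fell, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.295), with GPX4 at 0.65, GCLC at 0.75, GSR at -0.75 and NQO1 at -0.68. Of 15 apoptosis and atresia genes BAX rose by 0.70 and TNFRSF1A by 0.42, the same adjusted over the list alone (camera adjusted p = 0.707), and IGFBP5 at 0.78 (0.36 without large-follicle replicate 1) and MCL1 at -0.22 did not pass. Of 16 unfolded protein response genes DDIT3 rose by 1.22 and PDIA4 fell by 0.81, the same adjusted over the list alone (camera adjusted p = 0.775), and HSPA5 at -0.30 and DNAJC3 at -0.27 did not pass. Of 25 ribosomal protein genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.759), with RPL4 at -0.14, RPL7A at 0.10 and RPS19 at -0.22. Median, mean and camera direction differed in sign for the unfolded protein response (median 0.03, mean 0.01, camera down) and the apoptosis list (median -0.01, mean 0.09, camera up). Leaving out 1 array, the mean of the unfolded protein response ran from -0.04 to 0.06.

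**Figure D4:**
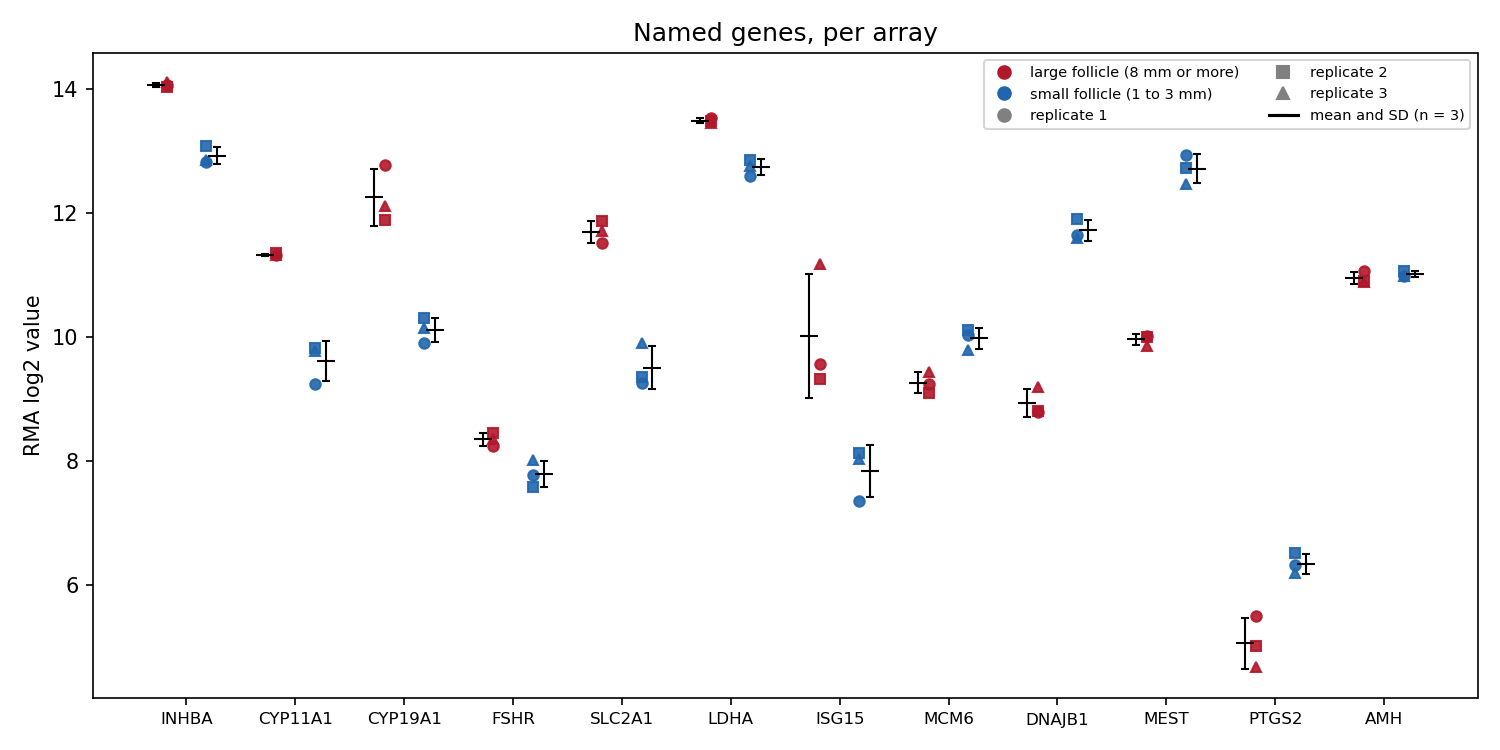
For 12 named genes the vertical axis gives the RMA log2 value; coloured points are arrays (shape gives the replicate) and black bars the mean and SD of each group (n = 3). CYP19A1 averaged 12.25 in large-follicle and 10.12 in small-follicle arrays, DNAJB1 8.93 and 11.72, and AMH, which did not pass, 10.95 and 11.01.

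Markers of other cell types gave some calls, in both directions, where 12.9% of all probe sets tested were called. Of 9 measured oocyte markers 0 passed, also adjusted over the list alone, with OOEP at 0.40, UCHL1 at -0.15 and BMP15 at 0.16. Of 9 theca and interstitial markers 1 rose, APOD, also adjusted over the list alone, whereas DLK1 at 0.17 and APOE at 0.21 did not pass. Of 14 endothelial markers 2 fell (TEK by 0.57 and FLT1 by 0.74), also adjusted over the list alone, with VWF at 0.46 not passing (camera's Benjamini-Hochberg adjusted p = 0.972, direction up against a mean of -0.02 and a median of 0.06). TEK averaged 3.44 against 4.01, a low signal on these arrays. Of 11 smooth muscle and stroma markers 2 rose, TAGLN by 1.67 and CNN1 by 0.66, and MYLK fell by 0.78, with 3 and 1 adjusted over the list alone (camera's Benjamini-Hochberg adjusted p = 0.707, median -0.04, mean 0.14). That mean ran from 0.08 to 0.24 leaving out 1 array. Of 7 red cell markers 1 rose, HBM by 1.54, also adjusted over the list alone, with HBA at 0.40 and AHSP at 0.19 not passing. Of 8 surface epithelium markers 1 rose, KRT18 by 1.91, also adjusted over the list alone, with UPK3B at 0.29 and KRT8 at 0.20 not passing.

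Of the 29 lists fixed, 24 held at least 10 measured genes and were tested, and 6 passed camera with the preset correlation, 4 upward and 2 downward. None passed with an estimated correlation, the smallest adjusted p being 0.455, and fry, which tests whether a list moves on balance 1 way, passed 7. Of the 6, fry did not pass the mitotic cell cycle (Benjamini-Hochberg adjusted p = 0.162), DNA replication (adjusted p = 0.111) and the interferon response (adjusted p = 0.075). It passed 4 that camera did not, DNA repair (adjusted p = 0.00864), smooth muscle and stroma markers (adjusted p = 0.0178), IGF and growth factor signalling (adjusted p = 0.0258) and immediate early and heat shock genes (adjusted p = 0.0404). With other splits of the same 6 arrays into 3 and 3, camera with the preset correlation passed up to 7 lists.

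Of the 94 called genes that the rule for named genes picked, 64 kept their call whichever array was left out and 30 lost it at least once, 23 without large-follicle replicate 1, 23 without large-follicle replicate 2, 12 without large-follicle replicate 3, 26 without small-follicle replicate 1, 27 without small-follicle replicate 2 and 10 without small-follicle replicate 3. All 30 kept their sign, as genes whose groups do not overlap must when an array is left out. No value of these 30 moved by more than 1.45 times. Ranges cover the fits that lost the call. BMPR1B (0.38 to 0.63), S100A9 (0.33 to 0.47) and SOD2 (-0.47 to -0.34) lost the call in all 6 fits. Besides FSHR, the calls of BMPR2 (0.42 to 0.60), GADD45A (0.49 to 0.67), IGF2R (-0.43 to -0.33), MAD2L1 (-0.48 to -0.39), MYLK (-0.83 to -0.63), NQO1 (-0.74 to -0.52) and TNFRSF1A (0.35 to 0.49) were lost in 5. Lost in 4 were ACSL3 (-0.62 to -0.51), CCNA2 (-0.87 to -0.80), CKS2 (-0.63 to -0.51), CORO1A (0.50 to 0.66), FANCI (-0.72 to -0.60), FLT1 (-0.82 to -0.55), GJC1 (-0.93 to -0.68), LCP1 (0.69 to 0.85), RSAD2 (0.64 to 0.89), TYMS (-0.75 to -0.65), VCAM1 (0.66 to 0.73) and VCAN (0.46 to 0.50). IRF7 (0.82 to 0.91), MCM4 (-0.73 to -0.63) and TIMP2 (0.44 to 0.52) lost it in 3, COL6A1 (-0.83 to -0.80) and TAGLN (1.57 to 1.60) in 2, and ISG15 (1.94) and MCM7 (-0.81) in 1, without small-follicle replicate 1 and 2 respectively.

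Of 33 genes that the rule named and that did not pass, 21 passed in no other setting. Leaving out 1 array brought calls for EBP (-0.76 without large-follicle replicate 3 and -0.80 without small-follicle replicate 3), ID1 (-0.60 without small-follicle replicate 3), OOEP (0.53 without small-follicle replicate 2), VWF (0.61 without large-follicle replicate 2) and CD14. EBP passed in 8 of 17 settings, DAAM1 in 6 of 18, MVK in 4 of 17 and HSPA5 in 3 of 18, so these lie close to the threshold. Among genes with small differences, leaving out 1 array gave values that ran for AMH from -0.12 to -0.03, BMP15 from 0.06 to 0.34, KRT8 from 0.08 to 0.35, RPL7A from 0.04 to 0.18, APOE from 0.12 to 0.31, DLK1 from 0.09 to 0.22, AHSP from 0.11 to 0.27, UPK3B from 0.18 to 0.40, RPS19 from -0.31 to -0.14 and UCHL1 from -0.22 to -0.09.

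Other probe sets of called genes did not pass in several cases, mostly with smaller values. This holds for MCM6 (0.03), TYMS (-0.02), LDHA (0.37 and 0.36), IRF7 (0.24 and 0.16), PDIA4 (-0.25 each), TIMP2 (0.22 and 0.35), COL6A1 (0.01 and -0.003), CD40 (0.05), KIT (-0.04 and -0.01), FLT1 (-0.09 and 0.11), PTGS2 (-0.14 and 0.06), BMPR1B (0.08), IGF2R (-0.31), CYP19A1 (0.07 and 0.13), S100A9 (0.53), VCAN (0.56) and MYLK (-0.71). Those of LAMC1 read -0.76, -0.73 and -0.46 (each called), -0.41 and 0.29, and other called ones of ACSL3 read -1.16 and -0.80. Those of CYP19A1, KIT, PTGS2, CD40 and BMPR1B, and that of FLT1 at -0.09, average below the lower quartile of probe set means (3.83) in both groups. The same holds for the uncalled probe sets of APOD and BMPR2 given above and for part of those of BOLA-DQB1.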

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

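Tests with the 3'-minus-5' index or the leukocyte markers as a covariate were chosen after the results were seen; the splits of the arrays were planned.

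The control probe sets, which the comparison of genes does not use, differed between the groups. The 3'-minus-5' index was lower in large-follicle arrays by a difference of -0.48 log2 units (1.98 ± 0.19 against 2.46 ± 0.27, SD, n = 3 each), in an exact permutation test with p = 0.1, the smallest that 3 against 3 arrays can give. Large-follicle replicate 1 (2.15) and small-follicle replicate 3 (2.16) lay close together. The index correlated with the groups at -0.785, so a covariate fit has a variance inflation of 2.60 and separates RNA quality from follicle size poorly. In that fit 199 of the 3094 calls were kept. The median size of their difference went from 0.64 to 0.57 and the median SE from 0.12 to 0.18, so the calls ended through the wider error as well as smaller differences. The mean of the mitotic genes went from -0.56 ± 0.24 (SE) to -0.18 ± 0.35 (SE), and that list no longer passed camera. The mean of DNA replication went from -0.60 ± 0.21 (SE) to -0.24 ± 0.28 (SE), and that list still passed camera. Both differences shrank, whereas the interferon list, whose error also grew, kept its difference and its call. What ended the mitotic call was not tested further.

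Interferon response genes were higher in large-follicle arrays, most in large-follicle replicate 3. Whether more leukocytes in these pools are the whole cause cannot be told. With the leukocyte markers as a covariate the mean difference was 0.95, no smaller than 0.85 ± 0.24 (SE) without it. Its 95% interval, -0.03 to 1.93, includes 0, so this explanation stays open. The list interferon response still passed camera at the preset correlation (Benjamini-Hochberg adjusted p = 5.04e-05, range over the alternatives 1.95e-05 to 0.591). Large-follicle replicate 3, at 0.87 for the interferon genes, had leukocyte markers at -0.22, below small-follicle replicate 3 at 0.22. Weaker RNA in the small-follicle arrays stays open in the same way. With the 3'-minus-5' index as a covariate the difference was 0.81, with a 95% interval from -0.63 to 2.26 that includes 0. Camera still passed at the preset correlation (Benjamini-Hochberg adjusted p = 0.00382). Without the covariate, camera with an estimated correlation gave adjusted p = 0.591. A biological difference between follicle sizes was not tested apart from these and stays open as well.

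Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For probe sets called by limma the real split gave 3094 and the highest other 0, so 1 split reached the real count. At an unadjusted p under 0.05 the counts were 6475 and 1693. Every other split puts arrays of both follicle sizes on each side, so the difference between the sizes widens the error of those fits. Few calls are then likely in them whatever caused that difference, so these counts cannot tell whether it arose by chance. For lists passing camera the real split gave 6 and the highest other 7, and 4 splits reached the real count.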

How the results depend on the processing

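Tests with covariates or with replicates 1 and 2 only were chosen after the results were seen. No called probe set changed sign in any fit. For fits that only leave out arrays this was fixed beforehand, since the groups overlapped in no called probe set. Of 94 called named genes, 22 passed in all settings and 64 in all leave-one-out fits; all 6 lists passed in every leave-one-out fit. Without 1 array, 787 to 1142 probe sets higher in large_follicle and 828 to 1337 probe sets lower in large_follicle were left; fewer arrays widen the error. With a replicate block 1034 were lower (930 higher), and FSHR was among the calls it ended. Same-numbered arrays correlated at -0.002, -0.054 and -0.343 in their deviations, so no pairing by number shows in the values. With so few arrays this cannot exclude a shared collection or day, which the labels do not give. With the 3'-minus-5' covariate 99 were higher and 116 lower, with the leukocyte covariate 745 and 912. At an unadjusted p under 0.05 and 1.5-fold 1012 were higher and 1095 lower. At a Benjamini-Hochberg adjusted p under 0.05 and 2-fold 291 and 202 were left, so more were higher than lower there. With 1 mean per gene 728 were higher and 745 lower, from fewer tests. The estimated correlation passed 0 lists by camera, against 6 at the preset. The within-group minus between-group mean correlation rose from 0.0087 to 0.0295 for probe sets above the median. The following changed direction without a call in either fit, and the cause was not tested. For lists the direction is camera's, beside the mean difference. The list cumulus expansion and ovulatory genes had 0.063 with the block and with trend and robust, 0.081 above the lower quartile, 0.126 with array weights, 0.229 in replicates 1 and 2, and -0.034 to 0.17 leaving out 1 array. The list gap junctions and cell contacts had -0.049 above the median, -0.031 with array weights, 0.012 with the 3'-minus-5' covariate, -0.055 in replicates 1 and 2, -0.037 with fry, and -0.049 to -0.023 leaving out 1 array. The list endothelial markers had -0.04 with quantile and with cyclic loess scaling, -0.012 with the leukocyte covariate, -0.006 with the mean over probe sets, -0.071 in replicates 1 and 2, -0.016 with fry, and -0.059 to 0.033 leaving out 1 array. The list apoptosis and follicular atresia had 0.038 with the 3'-minus-5' covariate and 0.015 to 0.15 leaving out 1 array. Replicates 1 and 2 gave 0.077 for the list extracellular matrix, 0.003 for the list cytosolic ribosomal proteins (-0.037 to 0.007 leaving out 1 array) and -0.03 for BMP15. Leukocyte markers gave 0 with their own covariate, by construction. In the 3'-minus-5' covariate fit RPL7A was -0.095, UCHL1 0.057, PTX3 -0.44 and AMH 0.026, and in the leukocyte covariate fit PTX3 was -0.627 and AREG -0.015. Leaving out 1 array, PTX3 ran from -0.29 to 0.72 and AREG from -0.015 to 0.225. Signal over background limits probe sets with means under the lower quartile (3.83), where differences are less certain.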

Other observations

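The low-oxygen and heat shock factor tests were set before their values were seen; the covariate tests, the test of immediate early genes and the grouping of heat shock proteins were chosen after the results were seen. Genes named here were chosen after their values were seen.

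Among 23 measured targets of low-oxygen signalling outside the lists of the report, 16 were higher in large-follicle arrays and 0 lower (limma, Benjamini-Hochberg). ADM, a vasodilator peptide, rose by 0.93, ERO1A, an oxidase of the endoplasmic reticulum, by 1.54, P4HA1, a collagen prolyl hydroxylase, by 0.88, VLDLR by 0.81 and the histone demethylase KDM3A by 0.74. Camera in limma, 2-sided and Benjamini-Hochberg adjusted over the 3 lists tested here, gave adjusted p = 4.56e-11 with the preset correlation and adjusted p = 0.134 with an estimated correlation, so the call depends on the assumed correlation. They go with EGLN3, NDRG1, SLC2A1 and VEGFA.

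A response to low oxygen in cumulus cells of large follicles is a candidate explanation for these increases. The median of the targets was 0.68, above the bound of 0.1 set beforehand. The list was drawn up after related genes were seen to rise in the same arrays. Passing the bound therefore shows that the targets rose together and cannot tell low oxygen from other causes of such a rise. Weaker RNA in the small-follicle arrays as the whole cause is argued against only as far as the 3'-minus-5' index measures it. With the index as a covariate the glycolysis list kept 0.55 (95% interval 0.22 to 0.88) of 0.78 ± 0.11 (SE). The targets kept 0.41 (0.17 to 0.66) of 0.61 ± 0.09 (SE). GAPDH is part of both the index and the glycolysis list, and the index separates RNA quality from follicle size poorly. Oxygen levels are not given in the sources used here, and whether a difference arose in the follicle or after collection stays open.

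Of 8 heat shock proteins in the handling list, 7 were lower in large-follicle arrays and HSPB1 was higher; they were grouped because they were seen to fall, so no set test of them is given. A shared heat shock factor programme is a candidate explanation: 13 other targets had a median of -0.20 (3 lower, HSPD1 at -0.45, CACYBP at -0.49 and CRYAB at -0.49; camera's Benjamini-Hochberg adjusted p = 0.0158, but adjusted p = 0.399 with an estimated correlation), a weak result. With the index as a covariate the heat shock proteins kept -0.77 (95% interval -1.24 to -0.30) of -1.04 ± 0.13 (SE). Since they were grouped after they were seen to fall, these values cannot decide whether weaker RNA is the whole cause. General handling stress stays open, since the 14 immediate early genes went both ways (3 higher, 2 lower, median -0.01, camera's Benjamini-Hochberg adjusted p = 0.812). How long the complexes of each group were handled is not given in the sources used here.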
